A study of Mus musculus with 6 samples.

How the data were processed

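Messenger RNA was measured in 6 libraries of cultured mouse nephrogenic stroma, 3 from low and 3 from high adhesion substrates. Per the labels' protocols, cells of the nephrogenic zone were released enzymatically from pooled kidneys, stained for PDGFRa and sorted, and RNA was isolated after 18 h of culture. A commercial service captured mRNA, reverse transcribed it and made libraries by tagmentation. The series' design text states that the low and high adhesion samples are litter-matched, and the sample titles number the litters 1 to 3. Replicates are therefore separate litters, each a pool of kidneys.

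Per the submitters' processing notes, the authors used FastQC 0.12.1, fastp 0.24.0, STAR 2.7.11, SAMtools 1.22.1, MultiQC 1.32 and featureCounts of Subread 2.1.1 with genome build GRCm39. Annotation release, strand setting, the treatment of reads that match several places and duplicate removal are not given in the sources used here. The authors deposited 1 table of 78409 genes with estimated counts per gene and library, not scaled. Between 7736 and 8256 genes per library had a fractional value, and these genes held 57.3% to 59.8% of the counts. Genes that overlap or share reads with copies elsewhere are thus uncertain, and antisense partners cannot be told apart without the strand setting. The table also holds CPM that the authors deposited, which differ from CPM computed from these counts by at most 5.1e-11. The table gives no symbol for 21909 genes, and these are named by identifier. The reference at hand was of build GRCm38 with GENCODE M21 annotation, so no coordinates are printed. It served only for transcript length and GC content by gene identifier, which 94.8% of tested genes and 98.2% of called genes had.

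Counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which kept 14834, and libraries were scaled by TMM (factors 0.988 to 1.011). A quasi-likelihood model with robust estimation held litter as a block and adhesion as the term tested, as the litter-matched design states, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05, two-sided. Log2 fold changes are high minus low adhesion. Their standard errors are the fold change divided by the root of the F statistic. Printed CPM use the TMM-scaled library sizes, with mean ± SD over 3 libraries. The biological coefficient of variation was 4.1% with the block and 10.7% without. A check of the pairing showed that same-litter libraries deviated together, with correlations of 0.58, 0.58 and 0.36 across genes for litters 1, 2 and 3 and of -0.49 to -0.08 between different litters. Deviations were taken from the group mean and sum to 0, so positive same-litter values push the others below 0 on average. Genes are not independent replicates. Without the replicate block 36 genes passed in place of 1416. Litter differences were tested in the same model with an F-test of 2 degrees of freedom.

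Before the data were examined, 35 gene lists were fixed for pathways, matrix and adhesion, renal stroma and other cell types of the kidney. The 34 lists with at least 5 tested members were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and 18 passed, 9 upwards and 9 downwards. None passed with a correlation estimated per list (lowest adjusted p = 0.253). In that setting the test itself, as well as the estimate, rests on 2 residual degrees of freedom. A list can therefore miss the threshold there without a high correlation. For the contractile list the estimate was 0.007, below the preset value, yet the unadjusted camera p went from 4.90e-18 to 0.0121. Lists at 0.253 are tied by the adjustment, with unadjusted camera p from 0.0121 to 0.0969. One passed with fry and 16 without the replicate block. Some genes belong to several lists.

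Genes were named by a rule fixed at the same time. It takes the 10 largest log2 fold changes in each direction among called genes with a mean of at least 5 CPM and the same direction in 3 of 3 litters, leaving out predicted, mitochondrial and ribosomal protein genes. It adds up to 4 called members of each list with the lowest adjusted p, or 2 of the highest mean CPM where none was called, then Fn1, Ccn1, Ccn2, Ankrd1, Acta2, Itga5, Foxd1 and Pdgfra, the 5 litter genes of lowest p, and sex-linked genes. Some genes that the rule takes are not reported here. Hsp90b1, Epcam and Spint2 in the report were chosen after their values were seen.

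The methods were tested on simulated data for 14834 genes with 200 changed at known folds. For the adhesion comparison the share recovered was 49.3% at 1.25-fold, 70.1% at 1.5-fold and 86.4% at 2-fold, or 73.3%, 95.7% and 100% among genes of at least 5 CPM. Unchanged genes were 6.2% of the calls. The simulated genes were independent and took their noise from the dispersions of the fit under test. The simulation therefore cannot show whether those dispersions are too low. The criterion for a working test was first set on all genes changed 2-fold, was not met, and was then, after this was seen, set on those of at least 5 CPM. In the simulated litter test 91% of genes changed 2-fold were called and 7.1% of the calls were unchanged genes. Libraries of a group were compared by chi-square over genes, and all pairs differed by 4.95 to 12.2 per degree of freedom, so none was a duplicate of another. The handling of PCR duplicates is not given in the sources used here, so the floor of 3 counts is taken to cover counting error only.

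Alternatives fixed in advance were RLE size factors, library size alone, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, leaving out mitochondrial genes, no replicate block, each litter left out, and each single library left out without the block. Leaving out genes with fractional counts, and a correction for transcript length and GC content fitted as splines per library with the litter block kept, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.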

Results

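Nephrogenic stroma is the interstitial connective tissue of the outer, nephron-forming zone of the fetal kidney. It was sorted by fluorescence for the surface receptor PDGFRa from pooled kidneys of wild-type CD1 mice at embryonic day 18, and its polyadenylated RNA was sequenced after 18 h of culture. The cells sat on coverslips coated with the silicone elastomer PDMS that had been incubated in 500 ng/mL bovine fibronectin (low adhesion, 3 libraries) or in 50000 ng/mL (high adhesion, 3 libraries). Each of 3 litters gave 1 library of each kind. The deposited counts summed to between 12596249 and 13508257 per library, so 1 count stood for 0.074 to 0.0794 CPM (counts scaled to a common library total) and 3 counts for 0.222 to 0.238 CPM. Protein-coding genes held 90.6% to 91.7% of the counts and mitochondrially encoded genes 1.69% to 2.32%. The design asks how the amount of fibronectin on the substrate changes the stromal transcriptome, with litter as a background difference between the pairs.

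The lists of contractile and cholesterol synthesis genes were higher at high adhesion in the camera test, and those of interferon-response and nephrogenic stroma genes lower. With an estimated correlation, where the test rests on 2 residual degrees of freedom, each had an adjusted p of 0.253. The adjustment tied these values, and the unadjusted camera p were 0.0121, 0.0969, 0.0716 and 0.0276 in that order. Nppb (ENSMUSG00000029019), which encodes the B-type natriuretic peptide, went from 82.1 to 165 CPM, a log2 fold change of 1.01 ± 0.05 (standard error, n = 3 each, edgeR adjusted p = 1.23e-13). Acta2 (ENSMUSG00000035783), smooth muscle actin, rose 1.45-fold from 3950 ± 1277 to 5664 ± 1556 CPM (SD, n = 3 each, edgeR adjusted p = 5.88e-11). Pdgfra (ENSMUSG00000029231), whose product the cells were sorted on, fell 1.46-fold from 30.8 ± 3.71 to 21.1 ± 4.64 CPM (SD, n = 3 each, edgeR adjusted p = 1.59e-05). Foxd1 (ENSMUSG00000078302), a transcription factor of stromal progenitors, fell 1.20-fold from 205 ± 19.1 to 170 ± 12.4 CPM (SD, n = 3 each, edgeR adjusted p = 8.00e-05). The SDs hold the spread between litters, whereas these tests rest on changes within litters. Without the replicate block Nppb passed (edgeR adjusted p = 0.0106), and Acta2, Pdgfra and Foxd1 did not (edgeR adjusted p = 0.699, 0.325 and 0.338).

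Of 14834 genes tested, 1416 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with litter in the model, 699 higher and 717 lower at high adhesion. Most changes were small. The median absolute log2 fold change of the called genes was 0.32, 290 of them changed at least 1.5-fold and 56 at least 2-fold, the latter split 28 and 28. Of the called genes 1403 moved in the same direction in 3 of 3 litters, an agreement that a model with litter as a block selects for. Without the replicate block only 36 genes passed (20 higher, 16 lower, all 36 among the 1416), with 1359 at an unadjusted p under 0.05. DESeq2 called 406 genes with the block and 122 without the replicate block, and leaving out litter 3 gave 908 in edgeR. Of the genes named here, Bcar1 and Fdps held fractional counts in 6 of 6 libraries and Ccn2, Serpine2, Isg15, Phgdh, Runx2 and Krt8 in 5 of 6, so their values are uncertain.

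**Figure D1:**
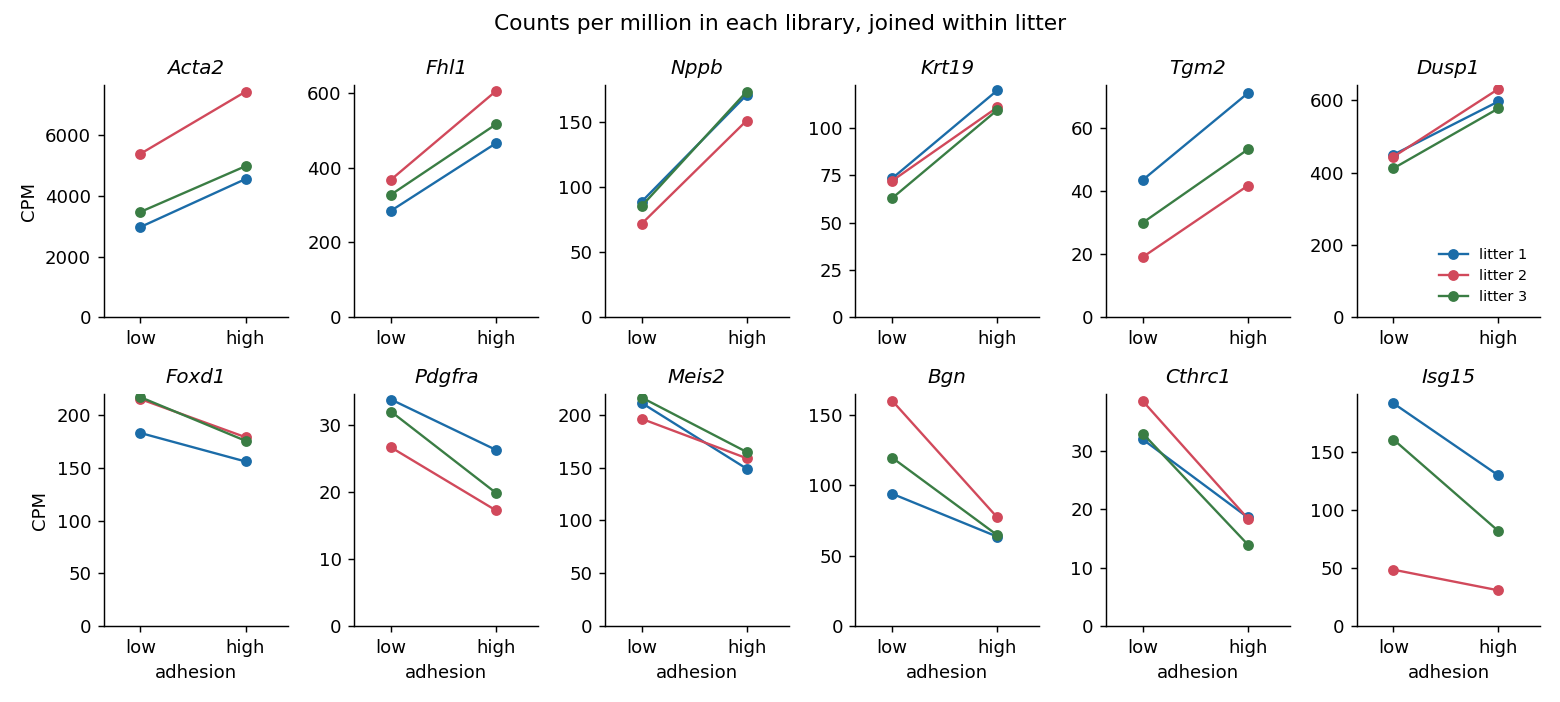
CPM (vertical axes, each starting at 0) of 12 genes in the 6 libraries, at low and high adhesion (horizontal axes), with the 2 libraries of a litter joined by a line. The upper 6 genes were higher and the lower 6 lower at high adhesion in each of the 3 litters, and Acta2 and Isg15 show litters that lie further apart than the adhesion groups.

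Among the 10 genes with the largest rise, of called genes of at least 5 CPM, were Siglecg, Ripor2, Tubb3, Synpo2l, Nppb, Ppargc1b, Lmod1, Wnt4 and Bex1. The folds of these ran from 2.22 for Siglecg to 1.85 for Bex1. Tubb3, a neuronal tubulin, rose from 4.39 ± 1.65 to 9.30 ± 2.57 CPM, and Wnt4, a secreted inducer of nephron epithelium, from 3.98 ± 0.37 to 7.55 ± 1.94 CPM (SD, n = 3 each). The 10 with the largest fall were Car8, Gja3, Pdzrn3, Dkk1, Rab27b, Cthrc1, Cplx2, Baalc, Ifit1 and Kit, with falls from 2.66-fold for Car8 to 1.96-fold for Kit. Dkk1, a secreted inhibitor of Wnt signalling, went from 16.0 ± 3.30 to 7.58 ± 2.31 CPM, and the secreted matrix protein gene Cthrc1 from 34.5 ± 3.53 to 17.0 ± 2.63 CPM (SD, n = 3 each). Without the replicate block Ripor2, Nppb, Bex1, Pdzrn3, Cthrc1 and Cplx2 were still called, with adjusted p from 0.0106 for Nppb to 0.0481 for Bex1 and Cplx2, and the other 13 named here were not.

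Of 30 tested members of the list of contractile genes and targets of the actin-regulated transcription factors SRF and MRTF, 15 rose, 2 fell and 13 did not pass (21 and 2 rose and fell when adjusted over the list alone). Fhl1 rose 1.62-fold, Lmod1 1.90-fold and Cnn1, calponin, 1.73-fold. The fibronectin receptor subunit Itga5 was 1 of the 2 members that fell, by 0.26 on the log2 scale (edgeR adjusted p = 0.000215). Of 27 targets of the mechanosensitive coactivators YAP and TAZ, 12 rose and 2 fell (15 and 3 when adjusted over the list alone), with log2 fold changes of 0.38 for Tgfb2, 0.49 for Gadd45a and 0.24 for Amotl2. The usual reporters of that pathway moved little. Ankrd1 rose 1.16-fold (edgeR adjusted p = 0.0024), Ccn1 had a log2 fold change of 0.08 (adjusted p = 0.162) and Ccn2 one of 0.10 (adjusted p = 0.0554). Ccn2 passed with limma-voom (adjusted p = 0.00911) and in 3 further settings. Immediate early genes rose in 11 and fell in 2 of 26 cases (13 and 3 when adjusted over the list alone). Dusp1, a MAP kinase phosphatase, rose 1.38-fold, Fosl1 1.35-fold and Klf2 1.28-fold, while Junb fell by 0.34 on the log2 scale. The camera list test gave adjusted p of 8.34e-17 for the contractile list, 5.27e-05 for the YAP and TAZ list and 3.92e-05 for immediate early genes. With an estimated correlation between genes the adjusted p was 0.253 for each of these lists, in a test that rests on 2 residual degrees of freedom. The estimates were 0.007, 0.06 and 0.063 in that order. The contractile estimate lies below the preset 0.01, so correlation between its genes does not account for the loss of that call.

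Of 21 tested members of the nephrogenic stroma progenitor list 11 fell, 2 rose and 8 did not pass (14 and 3 when adjusted over the list alone; camera adjusted p = 5.83e-11, adjusted p = 0.253 with an estimated correlation). Rarb, a retinoic acid receptor, fell 1.74-fold, the growth factor gene Fgf7 1.59-fold, and the homeobox gene Meis2 fell by 0.40 on the log2 scale. Osr1, an early kidney mesenchyme transcription factor, rose 1.63-fold. Genes for stromal signals to nephron progenitors fell in 9 and rose in 3 of 29 cases (12 and 4 when adjusted over the list alone; camera adjusted p = 0.00669, adjusted p = 0.253 with an estimated correlation). The guidance cue Ntn1 fell 1.46-fold there, and Tgfb2 and Wnt4 were among those that rose. In the TGF-beta and BMP list 8 of 22 members fell and 1 rose (13 and 2 when adjusted over the list alone; camera adjusted p = 1.21e-06, adjusted p = 0.253 with an estimated correlation). Bmper, Ltbp2 and Pmepa1 fell 1.69-fold, 1.67-fold and 1.34-fold, and the 1 that rose was Nog (1.67-fold), which encodes the secreted BMP antagonist noggin. Adipogenic and chondrogenic genes fell in 5 of 13 cases with no rise (5 when adjusted over the list alone; camera adjusted p = 0.0026, adjusted p = 0.253 with an estimated correlation), among them Pparg (1.47-fold lower) and Runx2 (1.23-fold lower).

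The gene for fibronectin itself did not pass the test, with 777 ± 64.7 CPM at low and 748 ± 107 CPM at high adhesion (SD, n = 3 each, edgeR adjusted p = 0.438), but without litter 2 its log2 fold change of -0.13 passed (adjusted p = 0.0279). Of 33 matrix genes 12 fell and 4 rose (16 and 5 when adjusted over the list alone; camera adjusted p = 6.78e-05, adjusted p = 0.253 with an estimated correlation). The proteoglycan gene Bgn fell 1.79-fold and the fibrillar collagen gene Col3a1 1.26-fold, while the basement membrane collagen gene Col4a1 and the protease inhibitor gene Timp3 rose 1.18-fold and 1.24-fold. Focal adhesion and integrin genes went both ways, 6 higher and 7 lower of 30 (11 and 9 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.507). Itga3 rose 1.67-fold and Bcar1 1.21-fold, while Itgav fell 1.24-fold and Itga5 1.20-fold. Among matrix proteases and their inhibitors 4 rose and 3 fell of 21 (4 and 5 when adjusted over the list alone; camera adjusted p = 0.843), with Adamts5 1.45-fold higher and Serpine2 1.36-fold lower.

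**Figure D2:**
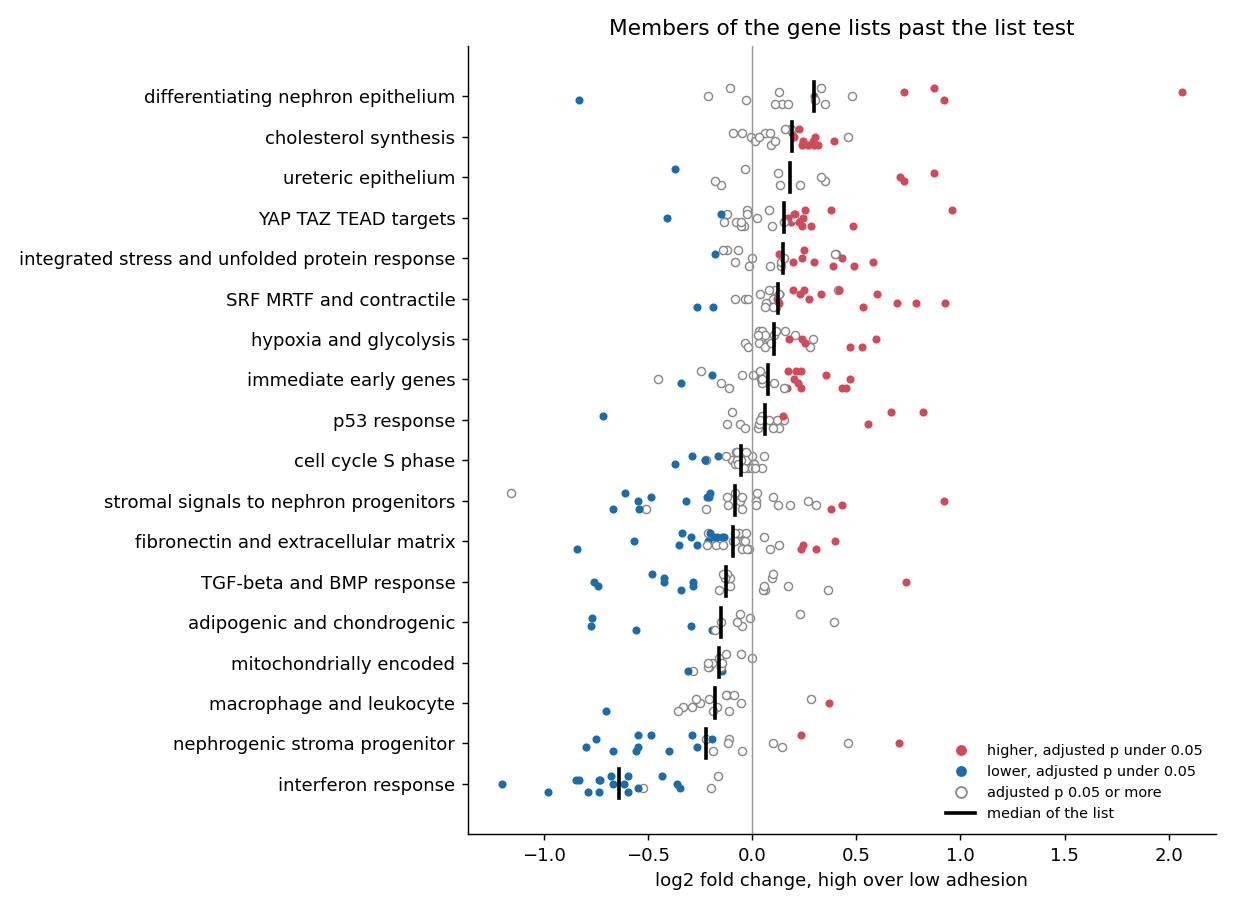
Log2 fold change of high over low adhesion (horizontal axis) for each tested member of the 18 gene lists past the list test (vertical axis, ordered by median). Filled points passed the gene test, red for higher and blue for lower, open points did not, and the black bar is the list's median, which runs from -0.64 for interferon response to 0.30 for differentiating nephron epithelium.

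Interferon-response genes moved furthest as a group. Of 20 tested members 17 fell and none rose (18 and 0 when adjusted over the list alone), with a median log2 fold change of -0.64 (camera adjusted p = 1.17e-27, adjusted p = 0.253 with an estimated correlation). Isg15 went from 134 ± 75.2 to 80.8 ± 49.4 CPM (SD, n = 3 each), and Bst2, which encodes the antiviral protein tetherin, fell 1.51-fold. All 20 members also differed between litters in the edgeR litter test. Without the replicate block neither gene passed (adjusted p = 0.849 and 0.861). Macrophage and leukocyte markers, measured in the same libraries, had a median of -0.18, with 1 of 16 lower (Cd14, 1.63-fold) and 1 higher (Lyz2, 1.29-fold; 1 and 1 when adjusted over the list alone). Lyz2 did not pass in DESeq2 (adjusted p = 0.373) or without litter 1 (adjusted p = 0.282). That list passed narrowly (camera adjusted p = 0.0338) and did not with an estimated correlation (adjusted p = 0.334), without the replicate block (adjusted p = 0.188), without litter 2 (adjusted p = 0.268) or over genes of at least 5 CPM (adjusted p = 0.0588). Inflammatory and NF-kB genes fell in 6 and rose in 2 of 23 cases (6 and 2 when adjusted over the list alone), and their list missed the threshold (camera adjusted p = 0.0546), passing without litter 1 (adjusted p = 0.0276), over genes of at least 5 CPM (adjusted p = 0.0174) and with a length and GC correction chosen after the data were seen (adjusted p = 0.0491). With all litters and an estimated correlation the adjusted p of this list was 0.363. The cytokine gene Il11 fell 1.82-fold and the chemokine gene Ccl2 1.48-fold, while Tnfaip3, an inhibitor of NF-kB, rose 1.72-fold.

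Cholesterol synthesis genes rose in 12 of 24 cases and fell in none (14 and 0 when adjusted over the list alone; camera adjusted p = 1.38e-08, adjusted p = 0.253 with an estimated correlation), with Insig1 1.23-fold and Fdps 1.21-fold higher. In the list of integrated stress and unfolded protein response genes 10 of 23 rose and 1 fell (11 and 1 when adjusted over the list alone; camera adjusted p = 1.77e-05, adjusted p = 0.363 with an estimated correlation). The members of lowest adjusted p were Phgdh (1.35-fold), of serine synthesis, the lipoprotein receptor gene Vldlr (log2 fold change 0.58), Asns (1.31-fold), of asparagine synthesis, and Shmt2 (1.23-fold), of glycine synthesis. The member that fell, by 0.18 on the log2 scale, was the endoplasmic reticulum chaperone gene Hsp90b1. Hypoxia and glycolysis genes rose in 6 of 23 cases and fell in none (7 and 0 when adjusted over the list alone; camera adjusted p = 9.71e-05, adjusted p = 0.253 with an estimated correlation), among them the glucose transporter gene Slc2a1 (1.19-fold) and Vegfa (1.18-fold). Vegfa did not pass in DESeq2 (adjusted p = 0.223) or without litter 3 (adjusted p = 0.157). The fry test, which asks whether a list's genes move on balance one way, kept only the hypoxia list (adjusted p = 0.00233). In the p53 list 4 of 18 rose and 1 fell (4 and 1 when adjusted over the list alone), with Perp 1.47-fold and Pmaip1 1.58-fold higher and Fas 1.64-fold lower, the last not called by DESeq2 (adjusted p = 0.0901). The list passed (camera adjusted p = 0.0062), but not with an estimated correlation (adjusted p = 0.363), without the replicate block (adjusted p = 0.0775) or without litter 1 (adjusted p = 0.0719).

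Replication genes of the S phase fell in 4 of 25 cases and rose in none (5 and 0 when adjusted over the list alone; camera adjusted p = 0.00975, adjusted p = 0.509 with an estimated correlation). Hells fell by 0.29 on the log2 scale, and without litter 3 the list did not pass (adjusted p = 0.125). Mitotic genes fell in 4 and rose in 2 of 25 cases (4 and 2 when adjusted over the list alone; camera adjusted p = 0.418), with Cenpf 1.35-fold lower. Mitochondrially encoded genes fell in 2 of 13 cases and rose in none (3 and 0 when adjusted over the list alone; camera adjusted p = 0.000302, adjusted p = 0.577 with an estimated correlation). Their share of counts was 2.32% in the low adhesion library of litter 1 and between 1.69% and 2.1% in the other 5 libraries, and without litter 1 the list did not pass (adjusted p = 0.682).

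Markers of other renal cell types were compared between the substrates, which does not measure how pure the sort was. Both epithelial lists passed upwards, with adjusted p of 0.253 with an estimated correlation for each. In the ureteric list 3 of 12 rose and 1 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 2.34e-05), and the 3 that rose were the keratin genes Krt19, Krt18 and Krt8. Krt19 went from 69.5 ± 5.71 to 114 ± 5.61 CPM and Krt18 from 335 ± 148 to 546 ± 200 CPM (SD, n = 3 each). Gata3 fell 1.29-fold, and Epcam, the general epithelial marker, was 5.93 CPM at low and 7.46 CPM at high adhesion, above in 3 of 3 litters but not past the test (edgeR adjusted p = 0.1). Spint2, a protease inhibitor gene of epithelia, rose 1.33-fold (edgeR adjusted p = 0.0263). In the list of differentiating nephron epithelium 5 of 17 rose and 1 fell (6 and 1 when adjusted over the list alone; camera adjusted p = 7.41e-05), with Cldn6 at 0.557 ± 0.157 and 2.36 ± 0.532 CPM (SD, n = 3 each) and Cdh6 1.78-fold lower. Krt18 and Krt8 belong to both epithelial lists and are among these 5, so the lists are not separate evidence.

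The lists for the remaining cell types and pathways did not pass. For medullary stroma 4 of 17 members rose and 3 fell (4 and 6 when adjusted over the list alone; camera adjusted p = 0.68), for the pericyte and renin lineage 3 of 12 rose and 4 fell (4 and 4; adjusted p = 0.883), and for nephron progenitors 2 of 18 rose and 2 fell (3 and 2; adjusted p = 0.578). Desmin (Des) rose 1.37-fold, while Pdgfrb fell 1.47-fold and the Wnt effector Lef1 1.36-fold. Podocyte markers rose in 1 of 7 cases (1 when adjusted over the list alone; adjusted p = 0.883), and endothelial markers rose in 1 and fell in 2 of 11 (1 and 2; adjusted p = 0.68), with the VEGF receptor gene Flt1 1.47-fold higher. No member of the erythroid list (7 tested, adjusted p = 0.334) or of the sex-linked list (5 tested, adjusted p = 0.889) passed, over all genes or when adjusted over the list alone. Without litter 3, however, the erythroid list passed downwards at the preset correlation (adjusted p = 2.04e-18). With all litters and an estimated correlation its adjusted p was 0.755. The neural list had 4 tested members, too few for the list test, of which Tubb3 and Elavl4 rose (2 when adjusted over the list alone). Elavl4 did not pass in DESeq2 (adjusted p = 0.455), without litter 1 (adjusted p = 0.0737) or without litter 2 (adjusted p = 0.12). Wnt and beta-catenin targets rose in 4 and fell in 3 of 16 cases (6 and 3 when adjusted over the list alone; adjusted p = 0.68), and retinoic acid genes rose in 2 and fell in 1 of 16 (2 and 2; adjusted p = 0.907), with Tgm2 1.82-fold higher. Notch genes rose in 1 of 9 (1 alone; adjusted p = 0.451), Hedgehog genes fell in 1 of 8 (2 alone; adjusted p = 0.23) and clock genes rose in 4 of 15 (4 alone; adjusted p = 0.0995). The median was below 0 where the list test pointed up for matrix proteases (-0.04), retinoic acid genes (-0.02) and podocyte markers (-0.06), and the mean was below 0 where it pointed up for matrix proteases and for nephron progenitors (-0.04).

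**Figure D3:**
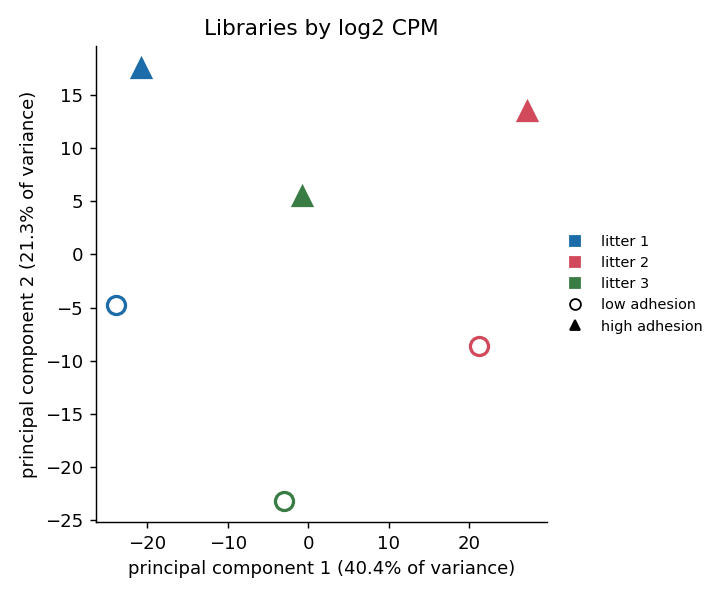
The 6 libraries on the first and second principal components of log2 CPM, which hold 40.4% and 21.3% of the variance. Colour gives the litter and shape the adhesion group, and litters 1 and 2 lie at opposite ends of the first component while the high adhesion library of each litter lies above its low adhesion partner on the second.

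More genes passed the litter test than the adhesion test, but the litter test has 2 degrees of freedom, so the counts are not a like comparison. Each litter was 1 pool, with its libraries on the 2 substrates as the only replicates. The litter p-values thus measure spread within pools, and litter cannot be told apart from the handling of its pool. In the edgeR test of the 3 litters, with adhesion in the model, 2655 genes passed an adjusted p of 0.05, and 636 of these also passed the adhesion test. Of the 30 tested contractile genes 28 passed the litter test. Some were higher in litter 2 than in litter 1, with a log2 difference of 3.39 for Actg2, enteric smooth muscle actin, 2.33 for Cnn1, 1.77 for Lmod1 and 0.78 for Acta2. Ccl2, Isg15 and Bst2 were lower in litter 2, with log2 differences from litter 1 of -1.54, -2.03 and -1.80, and no list was tested between litters. Of the 5 genes with the lowest p in the litter test, Actg2 rose with adhesion (1.52-fold), and Rps3a3, Gm9104, Rpl21-ps8 and ENSMUSG00000132147 did not pass the adhesion test. These 4 held fractional counts in 5 or 6 libraries and are uncertain, and Rps3a3, Gm9104 and Rpl21-ps8 carry names of pseudogenes or gene copies. Transcripts of both sexes were present in each group, with Xist at 114 ± 4.99 and 106 ± 6.88 CPM and the Y-linked Ddx3y at 46.1 ± 4.85 and 49.2 ± 5.84 CPM at low and high adhesion (SD, n = 3 each). DESeq2's likelihood ratio test called 866 genes for litter.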

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

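Leaving out genes with fractional counts, and the length and GC correction, were tests chosen after the data were seen. The 1416 genes of the adhesion test became between 1298 and 1479 with RLE size factors, library size alone, no filter, a mean of at least 5 CPM, limma-voom, mitochondrial genes left out and the length and GC correction, which kept 1258 of the 1416. The count was 406 with DESeq2 (207 higher, 199 lower), 36 with no replicate block (20 and 16), 122 with no replicate block and DESeq2 (65 and 57), and 651 with fractional genes left out (324 and 327), where 6128 genes were tested. Leaving out replicates gave 0 to 1553 genes, 0 to 734 higher and 0 to 819 lower, with 908 to 1553 for whole litters and 0 to 13 for single libraries without the block. The 2 fits lacking a litter 3 library called 0 genes in edgeR, with 1030 and 995 at an unadjusted p under 0.05. In fits of all 6 libraries or of whole litters, the 1416 genes that were tested kept their direction. The litter count of 2655 was 866 with DESeq2. The 18 lists became 0 with an estimated correlation and 1 with fry, and were 16 to 19 otherwise. Dropping the block ended the calls of the p53 and leukocyte lists and of no other list. Of 123 named genes with a call, 111 lost it with no replicate block, 27 with DESeq2 and 14, 7 and 16 without litters 1, 2 and 3. DESeq2 gave no adjusted p for some named genes, and the 27 leave these out. Signs turned only in fits without the block and 1 library. Over these, the log2 fold changes ran from -0.225 to 1.731 for Cnn1 and from -0.055 to 0.663 for Timp3, both lowest without the high adhesion library of litter 2, and from -0.15 to 0.77 for Lyz2, lowest without that of litter 1. In such fits the groups no longer hold the same litters. Cnn1 was 32.3 and 58.3 CPM in the low and high adhesion libraries of litter 2 and 7.33 to 17.8 CPM elsewhere. Leaving out 1 litter 2 library thus moves a group mean by a litter difference. Without the block, litter differences also count as noise, and the biological coefficient of variation was 10.7% against 4.1%. The cause of the other differences between settings was not tested. Depth and n limit small changes, since the self-test recovered 49.3% of the genes changed least.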

Other observations

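The genes of the next sentences, and every test of an explanation below, were chosen after the results were seen, and several versions of the tests for pericytes and epithelial cells were weighed before one was kept. Npr3, the clearance receptor of natriuretic peptides, was lower at high adhesion (189 against 113 CPM, log2 fold change -0.74 ± 0.05, standard error, n = 3 each, edgeR adjusted p = 1.71e-11), opposite to the peptide gene Nppb, and both moved one way in 3 of 3 litters. The small heat shock protein gene Hspb1 was higher (300.4 against 542 CPM, edgeR adjusted p = 1.23e-13), as was its pseudogene Hsp25-ps1 (log2 fold change 0.89). Hspb1 held fractional counts in 3 libraries and Hsp25-ps1 in 5, so both values are uncertain. Among cytokine receptor genes picked by eye, the log2 fold changes were -0.59 for Il1r1, -0.55 for Osmr and -0.51 for Lifr (edgeR adjusted p = 1.59e-07, 2.14e-06 and 1.85e-05), while Il6st, whose product pairs with those of Osmr and Lifr, had one of -0.08 (adjusted p = 0.461). The cell adhesion gene Alcam went from 420 to 284 CPM and the nonmuscle myosin gene Myh10 from 520 to 385 CPM (edgeR adjusted p = 2.27e-10 and 2.47e-08). Without the replicate block Hspb1, Il1r1 and Myh10 passed (adjusted p = 0.0103, 0.0197 and 0.0373), and Npr3, Osmr, Lifr and Alcam did not.

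Among genes in the top 10% by transcript length, 62 were called higher and 151 lower. The shortest 10% also leaned down, with 15 higher and 38 lower. Genes of middle length leaned up, with 88 higher and 66 lower in the 10% of median length 3397 bases. Once a length and GC trend was removed per library, these became 108 and 110, 26 and 32, and 74 and 78. That step removes such a skew largely by construction. Across genes, which are not independent replicates, the adhesion change and the difference of litter 2 from litter 1 had a Pearson correlation of 0.06. Of the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, 1 gave as many genes as the real one, which was the real one itself, with 1416 genes against 0 in each other split (edgeR with the litter block, 205 to 590 at an unadjusted p under 0.05). For gene lists 1 split reached the real 18, again the real one, and the highest other gave 13. The 3 other splits that part all litter pairs gave 2 to 11 lists. The remaining splits part 1 litter pair only, and some of them repeat the same fit. With the block, each of these contrasts low and high adhesion in 1 litter, and the 13 lists come from such a split. In every split but the real one the adhesion effect fell partly into the residual, so the 0 called genes say little about chance.

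Of 30 contractile genes 15 rose and 2 fell, and of 21 nephrogenic stroma genes 11 fell and 2 rose. With the length and GC trend removed both lists kept their direction, with camera adjusted p of 1.85e-15 for the contractile and 1.29e-11 for the stroma list (adjusted p = 0.253 for each in the uncorrected data with an estimated correlation), which argues against that trend as the whole cause. A larger share of pericytes was not settled by the 11 pericyte genes outside the contractile list, 4 of them in other lists too. Their median was 0.016 (SD 0.547), and 2 rose and 4 fell. The 2 that rose were Des (log2 fold change 0.458) and Myh11 (0.992), and Myh11 also serves as a smooth muscle marker below. The 4 that fell were Pdgfrb (-0.557), Rgs5 (-1.027), Cspg4 (-0.321) and Gata3 (-0.371), against a larger share. The others did not pass, among them Kcnj8 (0.016) and Abcc9 (0.386). A larger share of smooth muscle cells cannot be told apart from raised transcription, since Myh11, Cnn1, Lmod1 and Actg2 had a median log2 fold change of 0.856 (SD 0.173), which both would give. A complete sort for PDGFRa would remove cells without that receptor, but its purity was not measured here. A response of the stroma to adhesion remains an untested hypothesis beside these explanations.

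Interferon-response genes had a median log2 fold change of -0.64. Fewer leukocytes would lower their markers by a like amount, but the median of the 16 leukocyte genes, none of them in another list and none above 17.3 CPM on average, was -0.18 (SD 0.245). The fall was present in each litter, with medians of -0.48, -0.55 and -0.79 in litters 1, 2 and 3. A model with litter as a block selects for such agreement, so it is weak evidence against a cause in 1 litter. The list passed with the length and GC trend removed (camera adjusted p = 1.43e-28). With an estimated correlation between genes, 0.582 for this list, it did not pass (camera adjusted p = 0.253). That test rests on 2 residual degrees of freedom and cannot decide the question. A lower interferon response at high adhesion is a hypothesis.

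Of 6 keratin genes with at least 5 CPM, 5 rose (Krt7, Krt8, Krt18, Krt19 and Krt80), and Krt10 had a log2 fold change of -0.02. More epithelial cells, which a complete sort for PDGFRa would remove, would raise other epithelial genes as much. The other 22 members of the epithelial lists, 4 of them in further lists, had a median of 0.133 (SD 0.542). The keratin that rose least had 0.709. The margin between these is little more than the SD, and 3 of the 22 rose and 2 fell. Epcam, among the 22, had a log2 fold change of 0.332 without passing, and Spint2, outside these lists, rose by 0.411. The evidence against more epithelial cells is thus thin. Over the keratin and litter pairs with whole counts in both libraries, 11 pairs from 5 genes with Krt10 included, 9 were higher, with a median of 0.713 (SD 0.422). The keratins that rose did so in 3 of 3 litters, so their sign in these pairs was known before the test, and pairs of a gene are not independent. The values show only that the rise was also present where counts were whole, except for Krt8, which had no such pair. Raised keratin transcription in the stroma is a hypothesis.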
